A study of Mus musculus with 10 samples.

How the data were processed

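Gene expression was measured in the terminal ileum of 10 male mice of the C57BL/6JJmsSlc strain at 7 weeks of age, with 1 Affymetrix whole-genome mouse array per mouse, a 3'-biased array whose probe sets are placed near the 3' end of transcripts. Of the mice, 5 were controls and 5 had been put through subchronic mild social defeat, a protocol in which a mouse meets an aggressive mouse in short daily contacts. Per the labels' protocols, contact lasted 5 min on day 1 and was shortened by 0.5 min each day to 0.5 min on day 10. All mice received a purified AIN-93G diet and were fasted for 3 h before the ileum was taken. RNA was purified on RNeasy columns, and 100 ng of it was labelled with biotin by a 3' in vitro transcription kit, per the labels' protocols. Groups and mouse numbers came from the sample titles.

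The authors deposited 1 table of log2 probe set values for the 10 arrays, made with RMA (robust multi-array average, which corrects background, quantile-normalizes the arrays and summarises each probe set on a log scale) per the submitters' processing notes. The software and version of RMA are not given in the sources used here, and base 2 of the logarithm was taken from the usual output of RMA and from the range of the values, 1.22 to 14.4. The quartiles of the arrays lay close together, with array medians between 4.78 and 4.82, and no pair of arrays held identical values. RMA forces the arrays to a common distribution, so a change in total RNA per cell or in the share of all transcripts cannot be seen. Changes of genes close to background are understated on this scale. Array data carry no read depth, and the number of arrays limits the precision. Scanner output was not used here.

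The table held 45101 probe sets, of which 64 were the manufacturer's control probe sets. Of the others, 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 carried none. The Entrez identifiers of 34741 probe sets with 1 symbol were found in a RefSeq gene table, and 0 symbols changed by that update. Probe sets with several symbols or with none were left out of tests of genes. The lowest 40 percent of probe sets by their mean over the 10 arrays were left out, which set a floor of 4.15 on the log2 scale. Each gene was then represented by its probe set with the highest mean over all arrays, which left 13666 genes. For 7 of the genes that could be named, the gene's measured probe sets gave differences of opposite sign (Isl1, Tnfrsf19, Mcm5, Mcm2, Irf4, Egfl7 and Cs).

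Stressed and control mice were compared in R 4.3.3 with limma 3.58.1, which fits a linear model to each gene (lmFit) and moderates its variance over all genes (eBayes). P-values were adjusted by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p under 0.05. The comparison of all 10 arrays, the alternatives that left out each mouse in turn, 37 gene lists and the rule for naming genes were fixed before the data were examined. The array of control mouse 1 then stood apart from the others. Values without control mouse 1, 1 of the fixed alternatives, are therefore given as well as those of all 10 arrays, and every further setting for these 9 arrays was chosen after the data had been seen. Unless said otherwise, a difference is stressed minus control on the log2 scale with its standard error from limma, and a group value is a mean with the standard deviation (SD) over n mice.

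The 37 gene lists covered cell types, pathways and functions of the intestine. Lists were tested with limma's camera at a preset correlation between genes of 0.01, with camera at an estimated correlation and with fry as alternatives, each adjusted over the 37 lists. The list mean of each array, compared between groups by a 2-sided exact permutation test, was added after the data had been seen. Members were also counted at an adjusted p under 0.05 with adjustment over the list alone. The separation of the groups was measured as the share of the squared distance between arrays that lies between groups, and the spread as the median over genes of the log2 ratio of the SDs of stressed and control mice. Both had exact permutation tests over all assignments of the arrays, 1-sided for the separation and 2-sided for the spread.

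The rule for naming genes took up to 12 genes higher and 12 genes lower with the largest change among those called. Where fewer than 8 passed, it filled up to 8 by smallest p among genes that differed by at least 0.5 on the log2 scale, and passed over predicted and clone-named transcripts. It added up to 4 members by p of each list that shifted, up to 2 of the other lists, and members called over their list alone. Genes of the large intestine and posterior Hox genes were chosen as markers after control mouse 1 had been seen to stand apart.

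A further 3 measures were taken per array, chosen in part after the data had been seen. The RNA measure was the mean log2 ratio of the 3' to the 5' control probe sets of Actb and Gapdh. The clock phase score was the mean of clock output genes minus the mean of clock activator genes. The large intestine score was the mean of 10 measured marker genes of the large intestine.

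The procedure was tested on simulated data with the variance of the real arrays, in which genes varied independently of one another, unlike genes of a list in tissue. In groups of 5 and 5, 46.3% of 67 genes altered by 0.5 on the log2 scale and 94% of 67 genes altered by 1 were recovered, with 11 false calls among 13666 genes. In groups of 4 and 5 the shares were 65.7% and 100%, with 6 false calls. With both group sizes the 1 list that was shifted was called, and 0 lists were called in data without a shift. Because simulated genes varied independently, no simulated array stood apart over many genes, as control mouse 1 did among the real arrays. The results for groups of 5 and 5 therefore do not describe the real comparison that includes control mouse 1. Alternatives covered the filter on low values, the summary of probe sets, centring and quantile normalization of the deposited values, limma's trend and robust options, array weights, covariates for smooth muscle, Peyer patch and RNA quality, the replicate number as a block, the call threshold, tests of every probe set, the kind of list test, and leaving out each mouse. No genome coordinates are given because no genome build was given with the array values. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.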

Results

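Transcript levels in the terminal ileum were compared between 5 control mice and 5 mice that had gone through 10 days of subchronic mild social defeat. Each mouse was measured on 1 array, so n counts mice. The comparison addresses which ileal transcripts differ after repeated mild social stress. The 9 arrays other than that of control mouse 1 correlated with one another at 0.975 to 0.995 across genes, and control mouse 1 correlated with them at 0.918 to 0.947.

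Inducible defence genes of the epithelium and transcripts of lymphocytes and plasma cells were at lower levels in the ileum of stressed mice, and Fgf15, the ileal hormone that represses bile acid synthesis, was at a higher level. Fut2, the fucosyltransferase that adds fucose to glycans on epithelial cells, was at 8.53 ± 0.61 (SD, n = 5) in control mice and at 5.81 ± 0.69 (SD, n = 5) in stressed mice on the log2 scale. Car4, a membrane-bound carbonic anhydrase, was at 11.04 ± 0.23 (SD, n = 5) and 9.86 ± 0.29 (SD, n = 5). Fgf15 was at 6.40 ± 1.65 (SD, n = 5) in control mice, or 7.08 ± 0.77 (SD, n = 4) without control mouse 1, and at 8.81 ± 0.43 (SD, n = 5) in stressed mice. With all 10 arrays none of these genes passed the threshold over all genes, and the lower lists were called by camera at a preset correlation alone. There the defence list had an adjusted p = 0.165, the T cell list an adjusted p = 0.239 and the plasma cell list an adjusted p = 0.653 with an estimated correlation.

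With all 10 arrays, 0 of 13666 genes passed limma at a Benjamini-Hochberg adjusted p under 0.05, and 1069 genes (528 higher and 541 lower) were at an unadjusted p under 0.05. The smallest adjusted p in limma was 0.0605, for Fut2 and Car4. With array weights limma called 41 genes, and without stressed mouse 2 it called 2. Without control mouse 1, limma called 109 genes, of which 36 rose and 73 fell, and 2458 genes (1561 higher and 897 lower) were at an unadjusted p under 0.05. At an adjusted p under 0.1, 236 were higher and 230 lower. With 10 arrays, which include the same 9, 64 of these 109 were at an unadjusted p under 0.05. Over all genes tested, which are not independent of one another, the values of 4 control and 5 stressed mice did not overlap in 7.24%, against 1.59% expected by chance. The count of 109 became 19 without control mouse 2, 16 without control mouse 3, 58 without control mouse 4, 32 without stressed mouse 1, 21 without stressed mouse 3, 6 without stressed mouse 4, 14 without stressed mouse 5, and 108 and 154 without control mouse 5 and stressed mouse 2, each in addition to control mouse 1. It became 0 with the B cell and Peyer patch list mean, the clock phase score or the large intestine score as a covariate, and 31 with the 3' to 5' ratio of control transcripts.

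The epithelial defence list held antimicrobial and mucosal barrier genes that respond to microbes and cytokines. With control mouse 1 left out, 13 of its 19 measured members fell with adjustment over the list alone and 3 passed over all genes tested. With all 10 arrays, 8 members fell over the list alone and 0 passed over all genes. Fut2, without control mouse 1, fell by 2.56 ± 0.34 (SE) with a limma adjusted p of 0.0184. Duoxa2, the maturation factor of the hydrogen peroxide-producing oxidase Duox2, fell by 1.98 ± 0.27 (SE) with a limma adjusted p of 0.0184, from 6.95 ± 0.66 (SD, n = 4) to 4.97 ± 0.34 (SD, n = 5), and differed by -1.53 ± 0.46 (SE) with 10 arrays. Nos2, the inducible nitric oxide synthase, fell by 0.67 ± 0.11 (SE) with a limma adjusted p of 0.0301, against -0.48 ± 0.20 (SE) with 10 arrays. In control mouse 1 Duoxa2 was at 4.68, just below the lowest stressed mouse at 4.69, while Fut2 was at 9.16, above every other array.

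Retnlb, Saa1 and Saa2 of this list missed the threshold over all genes, and their values varied more among stressed than among control mice. Retnlb, which encodes the antibacterial goblet cell protein RELMβ, was at 8.74 ± 1.03 (SD, n = 5) in control mice and 5.07 ± 1.72 (SD, n = 5) in stressed mice. Retnlb was at 10.41 in control mouse 1, against at most 8.95 in the other controls. In stressed mouse 4 it was at 7.58, against at most 5.63 in the other stressed mice. Its limma adjusted p was 0.301 with 10 arrays and 0.0577 without control mouse 1. Saa1, a serum amyloid A gene of the epithelium, was at 13.11 ± 0.16 (SD, n = 5) and 10.32 ± 2.07 (SD, n = 5), and ranged in stressed mice from 6.94 to 12.39. Saa2 differed by -2.14 ± 0.45 (SE) with 10 arrays, with a limma adjusted p of 0.301. These 3 genes passed over the list alone both with and without control mouse 1. Of the 19 members, 7 were higher with 10 arrays and 3 without control mouse 1, since Reg3g, Reg3b, Reg3a and Cxcl16 changed direction. Reg3g, a bactericidal lectin at 9.39 in control mouse 1, differed by 0.13 ± 0.81 (SE) with 10 arrays and by -0.80 ± 0.19 (SE) without that mouse. Reg3b differed by 0.10 ± 0.33 (SE) and -0.28 ± 0.09 (SE), and Reg3a by 0.82 ± 1.07 (SE) and -0.43 ± 0.16 (SE).

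The mean of the defence list was 9.06 ± 0.46 (SD, n = 5) in control and 8.29 ± 0.37 (SD, n = 5) in stressed mice. The list was lower in limma's camera with all 10 arrays (adjusted p = 8.88e-07) and without control mouse 1 (adjusted p = 5.22e-11). With an estimated correlation the camera adjusted p was 0.165 and 0.0948. The exact permutation p of the list mean was 0.0318 with 10 arrays (0.160 adjusted over 37 lists) and 0.00794 without control mouse 1, the smallest that 126 assignments can give (0.0367 adjusted).

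**Figure D1:**
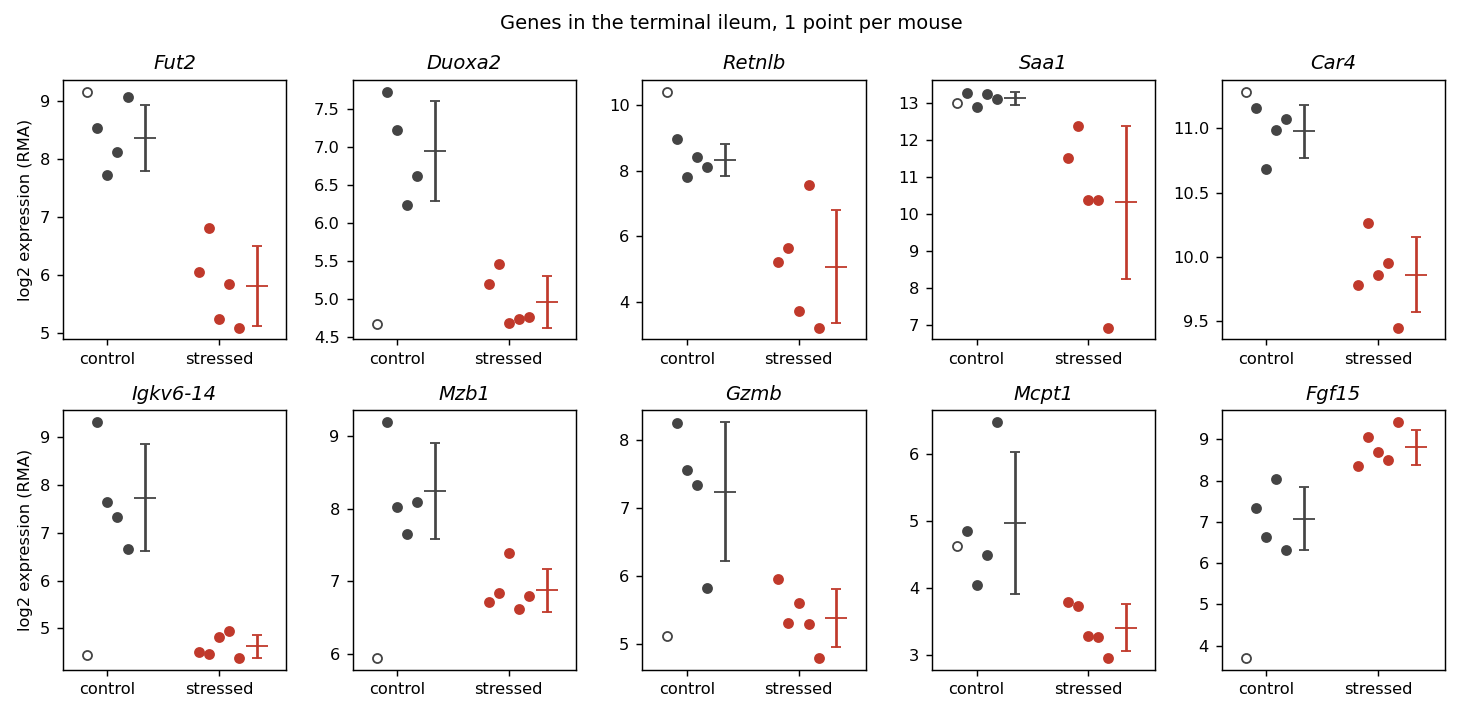
Expression of 10 genes on the log2 scale (y axis, RMA values) in control and stressed mice (x axis), 1 point per mouse, with control mouse 1 as an open circle and bars for the mean ± SD of the filled points (n = 4 control, n = 5 stressed). In the filled points the groups overlap for Gzmb alone, while control mouse 1 lies among or below the stressed mice for Duoxa2, Igkv6-14, Mzb1 and Gzmb. For Fgf15, which was higher in stressed mice, control mouse 1 lies below every other array.

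Other epithelial genes moved without belonging to the defence list. B3galt5, a galactosyltransferase of glycan chains, fell by 1.96 ± 0.25 (SE) without control mouse 1, with a limma adjusted p of 0.0184. It was at 7.19 ± 1.17 (SD, n = 5) in control and 4.75 ± 0.42 (SD, n = 5) in stressed mice with 10 arrays, where its limma adjusted p was 0.261. Control mouse 1 was at 9.11, against at most 7.19 in the other controls. B3galt5 and the immunoglobulin segment Igkv6-14 were called in limma whichever of the other 9 mice was also left out, with adjusted p up to 0.0476, and up to 0.241 over all 22 alternatives for B3galt5 and 0.136 for Igkv6-14. Fut2 was called in 8 of these 9 settings, with adjusted p up to 0.0541 in limma, and Duoxa2 in 7, also with adjusted p up to 0.0541 (up to 0.252 and 0.215 over all 22 alternatives). The other 20 genes that the naming rule took without control mouse 1 were called in 4 or fewer of the 9 settings. Car4 differed by -1.18 ± 0.15 (SE) with 10 arrays and fell by 1.12 ± 0.15 (SE) without control mouse 1, with a limma adjusted p of 0.0184.

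Transcripts of plasma cells and B cells were lower in stressed mice. With control mouse 1 left out, Igkv6-14, a variable segment of the kappa light chain, fell by 3.12 ± 0.40 (SE) with a limma adjusted p of 0.0184. It went from 7.74 ± 1.13 (SD, n = 4) to 4.62 ± 0.24 (SD, n = 5), and its probe set may take up related kappa segments. Mzb1, a chaperone of immunoglobulin assembly, fell by 1.36 ± 0.26 (SE, limma adjusted p = 0.0422), and Jchain, which joins dimers of IgA, fell by 0.85 ± 0.15 (SE, limma adjusted p = 0.0342). With 10 arrays the differences were -2.46 ± 0.68 (SE) for Igkv6-14, -0.90 ± 0.46 (SE) for Mzb1 and -0.50 ± 0.33 (SE) for Jchain, which in control mouse 1 was at 10.60, below every stressed mouse. Of 12 measured plasma cell and immunoglobulin genes, 9 fell and 1 rose over the list alone without control mouse 1. The gene that rose was Sdc1, a plasma cell marker that epithelial cells also express. Over all genes, 3 of the 12 passed. With 10 arrays 0 passed over the list alone, and Igkv6-14 was at 4.44 and Mzb1 at 5.95 in control mouse 1, within and below the range of the stressed mice.

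Of 13 measured B cell and Peyer patch genes, 8 fell over the list alone without control mouse 1 and 2 passed over all genes. Ly6d fell by 1.03 ± 0.16 (SE, limma adjusted p = 0.0245), and the B cell coactivator Pou2af1 fell by 1.28 ± 0.24 (SE, limma adjusted p = 0.0372). With 10 arrays 0 passed, Ly6d differed by -0.71 ± 0.31 (SE) and Pou2af1 by -0.77 ± 0.49 (SE), and both were lower in control mouse 1 than in any stressed mouse. Both lists were lower in camera, the plasma cell list at an adjusted p of 0.0115 with 10 arrays and 1.00e-08 without control mouse 1, and the B cell list at 3.82e-05 and 1.67e-08. The camera adjusted p with an estimated correlation was 0.653 and 0.165 for the plasma cell list, and 0.297 and 0.165 for the B cell list. The exact permutation p with 10 arrays was 0.246 for the plasma cell list mean (0.470 adjusted) and 0.103 for the B cell list mean (0.255 adjusted), and 0.00794 for either without control mouse 1 (0.0367 adjusted). With 10 arrays the plasma cell list lost its camera call without control mouse 2 (adjusted p = 0.229) and without control mouse 5 (adjusted p = 0.0554). That call also ended with the 3' to 5' ratio (adjusted p = 0.0919), the clock phase score (adjusted p = 0.225) or the B cell and Peyer patch list mean (adjusted p = 0.876) as a covariate, and with the lowest 60 percent of probe sets left out (adjusted p = 0.0645). The B cell list mean of control mouse 5 was 1.02 above the mean of the 10 arrays, and no other array was more than 0.26 above it.

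T cell and intraepithelial lymphocyte genes were lower in stressed mice in 19 of 20 measured members, both with and without control mouse 1. Without that mouse 15 fell over the list alone and 1 passed over all genes, the lymphocyte receptor Cd7, which fell by 0.39 ± 0.08 (SE, limma adjusted p = 0.0459) and differed by -0.33 ± 0.09 (SE) with 10 arrays. With all 10 arrays 9 fell over the list alone and 0 passed over all genes. The granzyme Gzmb, a protease of cytotoxic lymphocytes, was at 6.82 ± 1.30 (SD, n = 5) in control and 5.38 ± 0.43 (SD, n = 5) in stressed mice. Cd3g, a chain of the T cell receptor complex, was at 6.05 ± 0.57 (SD, n = 5) and 5.25 ± 0.17 (SD, n = 5), with a limma adjusted p of 0.408 over all genes and 0.0423 over the list alone. The list mean was 6.12 ± 0.40 (SD, n = 5) and 5.65 ± 0.09 (SD, n = 5), lower in camera at adjusted p of 4.29e-09 with 10 arrays and 5.78e-12 without control mouse 1. The camera adjusted p with an estimated correlation was 0.239 and 0.152. The exact permutation p of the list mean was 0.0318 with 10 arrays (0.160 adjusted) and 0.00794 without control mouse 1 (0.0367 adjusted).

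The mast cell genes Cpa3, Mcpt1 and Mcpt2 were each lower in all 5 stressed mice than in any of the 5 control mice. All their stressed values lay below the filter floor of 4.15, and Cpa3 was at up to 4.11 there against 4.15 in the lowest control. Control mouse 5 was highest for Mcpt1 (6.47) and Mcpt2 (7.10), where control mice 3 and 4 were at 4.05 to 4.58. Kit, also of this list, overlapped between the groups. Cpa3, the mast cell carboxypeptidase, fell by 0.48 ± 0.08 (SE, limma adjusted p = 0.0329) without control mouse 1 and differed by -0.42 ± 0.10 (SE) with 10 arrays. The mast cell proteases Mcpt1 and Mcpt2 differed by -1.49 ± 0.38 (SE) and -1.58 ± 0.40 (SE) with 10 arrays. Cpa3, Mcpt1 and Mcpt2 all passed over the list alone, with and without control mouse 1, of 7 measured genes of mast cells and eosinophils (17 were on the array). The list was lower in camera with 10 arrays (adjusted p = 0.000424) and without control mouse 1 (adjusted p = 0.0148). These became adjusted p = 0.146 and 0.152 with an estimated correlation. Its call without control mouse 1 ended with the B cell and Peyer patch list mean as a covariate (adjusted p = 0.409).

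Antigen presentation and interferon response genes were lower as groups. All 11 measured genes of MHC class II presentation were lower without control mouse 1, and 9 of them fell over the list alone, while 0 passed over all genes in limma. Over the list alone H2-Ab1 fell by 0.56 ± 0.15 (SE), and Cd74, the invariant chain, fell by 0.59 ± 0.20 (SE). With 10 arrays 10 of the 11 were lower and 0 passed either way, with H2-Ab1 at -0.46 ± 0.17 (SE) and Cd74 at -0.45 ± 0.22 (SE). The list was lower in camera at adjusted p of 2.06e-06 with 10 arrays and 2.35e-08 without control mouse 1. It was the 1 list that also passed with an estimated correlation without control mouse 1 (adjusted p = 0.0487), and with 10 arrays that adjusted p was 0.165.

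Of 40 measured interferon response genes, 35 were lower with 10 arrays and 38 without control mouse 1. Over the list alone 3 fell with 10 arrays and 9 without control mouse 1, where 1 passed over all genes, the nucleic acid sensor Zbp1, which fell by 1.06 ± 0.19 (SE, limma adjusted p = 0.0342) and differed by -0.99 ± 0.19 (SE) with 10 arrays. Cxcl9, a chemokine induced by interferon gamma, was at 7.18 ± 0.70 (SD, n = 4) in control mice without mouse 1 and 5.79 ± 0.59 (SD, n = 5) in stressed mice, and fell over the list alone but not over all genes (limma adjusted p = 0.0775), and differed by -1.02 ± 0.45 (SE) with 10 arrays. The list was lower in camera at adjusted p of 3.32e-09 with 10 arrays and 5.78e-12 without control mouse 1. With an estimated correlation the adjusted p was 0.297 and 0.268, and the exact permutation p of the list mean was 0.0714 and 0.0318 (0.203 and 0.0783 adjusted).

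**Figure D2:**
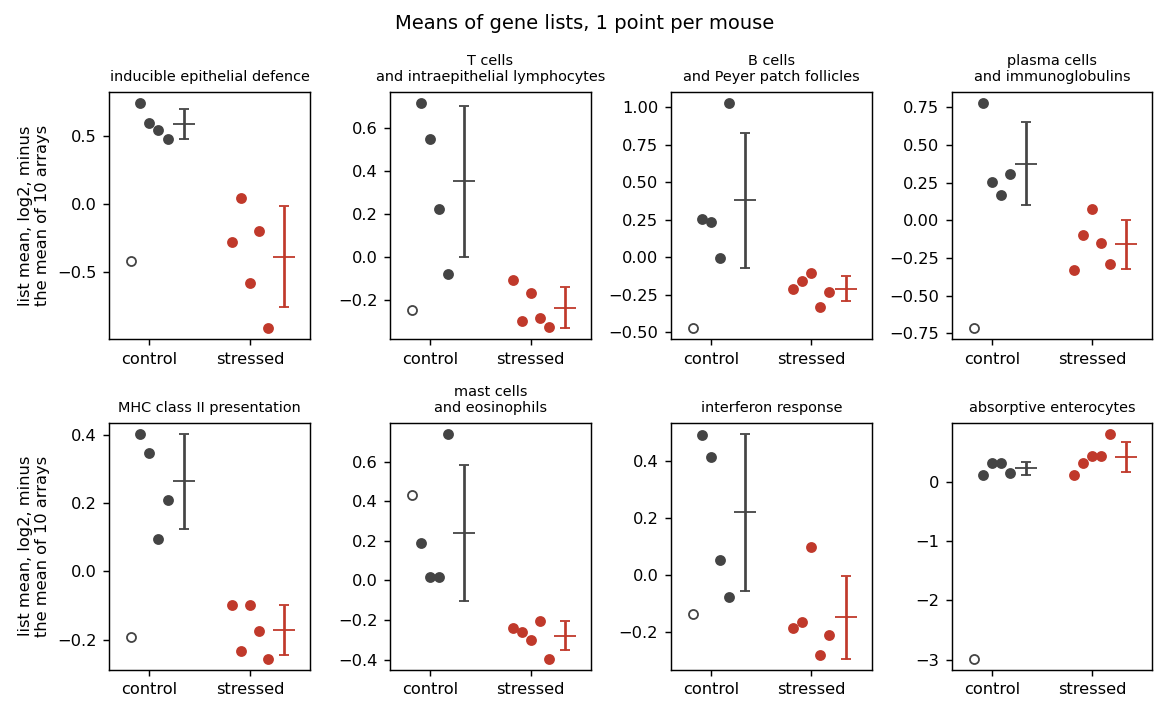
Means of 8 gene lists per array on the log2 scale, as the difference from the mean of the 10 arrays (y axis), in control and stressed mice (x axis), with 1 point per mouse, control mouse 1 as an open circle, and bars for the mean ± SD of the filled points (n = 4 control, n = 5 stressed). All 5 stressed mice lie below the 4 filled control points in every panel but those of interferon response and absorptive enterocytes, where control mouse 1 differs by -3.20 from the mean of the other controls.

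Fgf15, of the bile acid handling list, had the largest rise among the 109 genes called without control mouse 1, by 1.73 ± 0.32 (SE, limma adjusted p = 0.0347). In the same fit Cubn, the receptor for the vitamin B12 complex and a member of the absorptive enterocyte list, rose by 0.70 ± 0.11 (SE, limma adjusted p = 0.0245). Ppargc1a, a coactivator of mitochondrial genes in the mitochondrial respiration list, rose by 0.73 ± 0.11 (SE, limma adjusted p = 0.0245), while that list was not called in camera (adjusted p = 0.468). With 10 arrays Fgf15 differed by 2.41 ± 0.65 (SE, limma adjusted p = 0.373), Cubn by 1.35 ± 0.56 (SE, limma adjusted p = 0.600) and Ppargc1a by 0.46 ± 0.26 (SE, limma adjusted p = 0.730). In control mouse 1 Fgf15 was at 3.70 and Cubn at 7.18, below every other array, and Ppargc1a at 8.60, above every stressed mouse. The lists of absorptive enterocytes, bile acid handling and cholesterol synthesis were higher in camera with 10 arrays, at adjusted p of 5.85e-07, 0.00808 and 0.0118. The adjusted p with an estimated correlation was 0.485, 0.638 and 0.668. Without control mouse 1 the 3 lists were not called, at camera adjusted p of 0.0859, 0.468 and 0.366. In that comparison 9 of 22 other settings called the absorptive enterocyte list higher, and 1 called cholesterol synthesis lower, that without stressed mouse 3 (adjusted p = 0.0356). With 10 arrays the cholesterol synthesis list also lost its call without stressed mouse 3 (adjusted p = 0.105) and the bile acid list without stressed mouse 5 (adjusted p = 0.0503). Array weights ended both calls (adjusted p = 0.932 and 0.105), the smooth muscle list mean as a covariate ended that of cholesterol synthesis (adjusted p = 0.103), and leaving out the lowest 60 percent of probe sets ended that of bile acid handling (adjusted p = 0.0514). List means of control mouse 1 minus those of the other 4 controls were -3.20 for absorptive enterocytes, -2.01 for bile acid handling, -0.94 for cholesterol synthesis and -2.73 for Paneth cell products.

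Among the other genes that rose without control mouse 1 were Cpn1, a carboxypeptidase subunit, by 1.24 ± 0.25 (SE), Rdh16f2, a retinol dehydrogenase family member, by 1.11 ± 0.23 (SE), Tns4 by 0.99 ± 0.20 (SE), Trdmt1, a tRNA methyltransferase, by 0.95 ± 0.16 (SE), and Serpina1b, a serine protease inhibitor, by 0.94 ± 0.17 (SE). Cdh19, Tbc1d24, Plscr4, Prr15 and Dixdc1 rose by 0.70 to 0.78. The limma adjusted p of these 10 genes lay between 0.0238 and 0.0492. With 10 arrays none passed, and the differences were 0.80 ± 0.44 (SE) for Cpn1, 1.46 ± 0.37 (SE) for Rdh16f2, 0.81 ± 0.24 (SE) for Tns4, 0.85 ± 0.18 (SE) for Trdmt1, 2.05 ± 0.96 (SE) for Serpina1b, 0.48 ± 0.29 (SE) for Cdh19, 0.73 ± 0.12 (SE) for Tbc1d24, 0.49 ± 0.26 (SE) for Plscr4, 1.02 ± 0.27 (SE) for Prr15 and 0.29 ± 0.37 (SE) for Dixdc1. Cpn1 (8.13), Cdh19 (5.89), Plscr4 (7.54) and Dixdc1 (7.77) were higher in control mouse 1 than in any stressed mouse. Among the genes that fell were the methyltransferase Bhmt at -1.85 ± 0.35 (SE), the phospholipase Pla2g5 at -1.82 ± 0.29 (SE), the glycolytic regulator Pfkfb3 at -1.37 ± 0.25 (SE), another kappa variable segment at -1.31 ± 0.23 (SE), and the protease Prss27 at -1.28 ± 0.24 (SE), with limma adjusted p between 0.0262 and 0.0397. In the same order their differences with 10 arrays were -1.52 ± 0.44 (SE), -1.37 ± 0.48 (SE), -1.06 ± 0.36 (SE), -1.02 ± 0.33 (SE) and -0.84 ± 0.44 (SE), and Pla2g5 and Prss27 were lower in control mouse 1 than in any stressed mouse. Tat, tyrosine aminotransferase and a known glucocorticoid target in liver, fell by 1.34 ± 0.25 (SE, limma adjusted p = 0.0347), against -1.30 ± 0.24 (SE) with 10 arrays. The glucocorticoid response list as a whole was not called in camera, with 10 arrays (adjusted p = 0.363) or without control mouse 1 (adjusted p = 0.942), but was lower in both with the B cell and Peyer patch list mean as a covariate (adjusted p = 0.00802 and 0.0377). Of its 24 measured members 13 were higher and 11 lower with 10 arrays, where the test and the mean of the differences (-0.05) were negative and their median (0.03) positive.

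With all 10 arrays the naming rule took 8 genes in each direction, none of which passed. Besides Tbc1d24 and Trdmt1, the higher genes were the growth hormone receptor Ghr at 0.50 ± 0.09 (SE), transthyretin Ttr at 0.59 ± 0.11 (SE), catalase Cat at 0.51 ± 0.10 (SE), Vwa1 at 0.81 ± 0.16 (SE), Dgkd at 0.50 ± 0.11 (SE) and Reg4 at 0.85 ± 0.19 (SE). Besides Car4, Fut2, Tat, B3galt5 and Zbp1, the lower genes were Nrxn3 at -0.54 ± 0.09 (SE), the B cell oxysterol receptor Gpr183 at -0.51 ± 0.09 (SE) and the interferon-induced Ifit1bl1 at -1.38 ± 0.24 (SE). The limma adjusted p of these 9 genes lay between 0.252 and 0.303.

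By camera at the preset correlation, 15 of 37 lists shifted with 10 arrays (3 higher and 12 lower), 17 shifted without control mouse 1 (3 higher and 14 lower), and 12 did so in the same direction in both. With an estimated correlation 0 and 1 passed (7 and 10 at an unadjusted p under 0.05), with fry 0 and 8 (10 and 17 unadjusted), and by the exact permutation test of list means adjusted over 37 lists 0 and 8. Other divisions of the same 9 arrays gave up to 22 camera calls at the preset correlation, so the camera counts alone do not separate the groups from chance.

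Several genes of the large intestine were high on the arrays of control mouse 1 and stressed mouse 4. Car1, a carbonic anhydrase abundant in the colon, was at 14.17 in control mouse 1 and 13.32 in stressed mouse 4, and between 4.95 and 7.42 on the other 8 arrays. Cyp2c55 was at 13.05 and 11.62 on these arrays and at most 8.63 on the others, and the water channel Aqp8 was at 7.50 and 7.26 against at most 4.49. Control mouse 1 also had the homeobox gene Hoxd10 at 7.30 and Hoxa10 at 5.01, where the other controls were at most 2.85 and 2.24, and stressed mouse 4 had Hoxd10 at 4.46. The median over 10 measured large intestine genes was 1.09 for control mouse 1 minus the other controls and 0.376 for stressed mouse 4 minus the other stressed mice. In stressed mouse 4, 6 of the 10 were higher and 4 were lower, among them Insl5 at -0.52. In control mouse 1, 658 genes were more than 1 log2 unit above and 491 more than 1 below the mean of the other 4 controls. The large intestine score, without control mouse 1, was 6.56 ± 0.08 (SD, n = 4) in control and 7.04 ± 0.70 (SD, n = 5) in stressed mice (exact permutation p = 0.103, and 0.992 with 10 arrays).

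**Figure D3:**
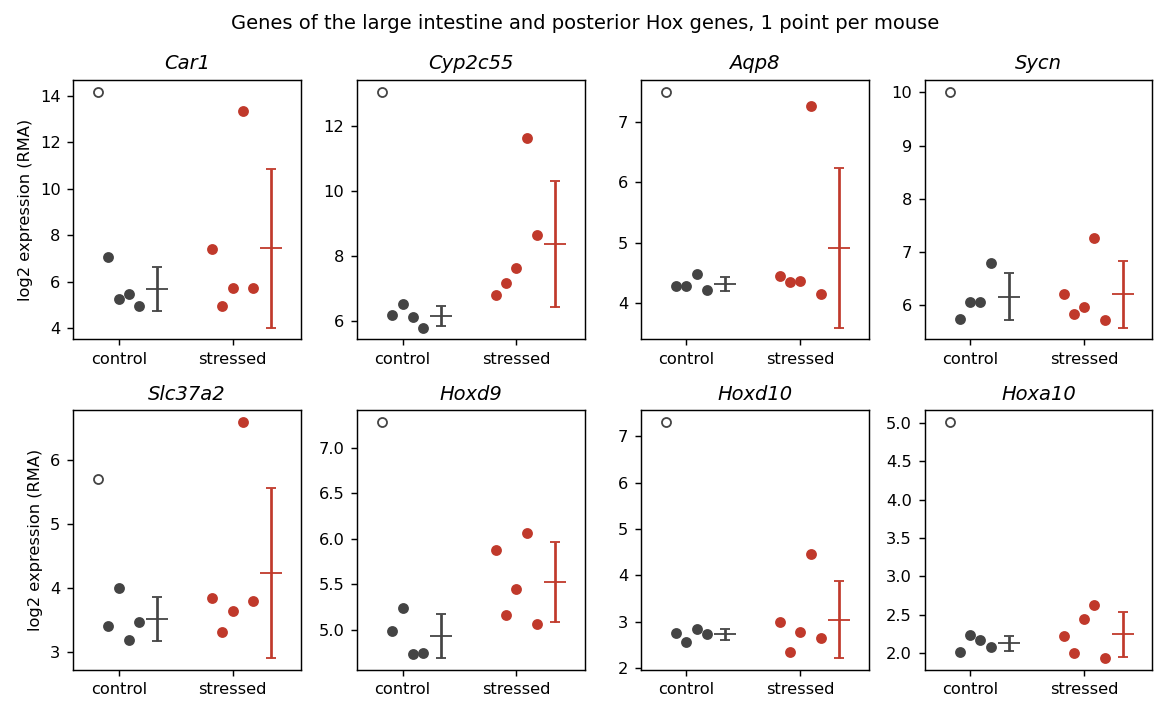
Expression of 5 large intestine genes and 3 posterior Hox genes on the log2 scale (y axis, RMA values) in control and stressed mice (x axis), with 1 point per mouse, control mouse 1 as an open circle, and bars for the mean ± SD of the filled points (n = 4 control, n = 5 stressed). Control mouse 1 is above all other arrays in 7 of the 8 panels, and in the Slc37a2 panel stressed mouse 4 is above it.

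Neither a score of clock genes nor a measure of RNA quality differed detectably between the groups. The clock phase score, which is higher where output genes such as Dbp are high and activators are low, was 0.13 ± 0.85 (SD, n = 4) in control mice without mouse 1 and 0.93 ± 0.69 (SD, n = 5) in stressed mice (exact permutation p = 0.167, and 0.238 with 10 arrays). It was between -0.48 and -0.13 in control mice 2 to 4, 1.38 in control mouse 5 and 1.03 in control mouse 1. Cry1, a repressor of the clock, fell by 0.76 ± 0.14 (SE, limma adjusted p = 0.0375) without control mouse 1 and differed by -0.61 ± 0.18 (SE) with 10 arrays. Without that mouse 6 of 18 measured clock genes passed over the list alone, 3 of them higher and 3 lower. The clock list was not called in camera (adjusted p = 0.395 without control mouse 1), which tests for a shift in 1 direction and can miss genes that move both ways. In fry's test for changes in either direction its adjusted p was 0.0373 without control mouse 1 and 0.3625 with 10 arrays. That test passed 27 of 37 lists without control mouse 1 and 3 with 10 arrays. The log2 ratio of 3' to 5' control transcripts was 0.54 ± 0.08 (SD, n = 4) without control mouse 1 and 0.70 ± 0.25 (SD, n = 5), highest in stressed mouse 1 at 1.13 (exact permutation p = 0.302, and 0.262 with 10 arrays).

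Over all genes, the groups accounted for 14.8% of the squared distance between the 10 arrays (exact permutation p = 0.103) and for 30.2% without control mouse 1 (exact permutation p = 0.00794, the smallest that the design allows). The axis of largest variance, with 55.6% of the total, set control mouse 1 against the other 9 arrays. The next axis, with 15.3%, differed between groups (exact permutation p = 0.00794). The spread between animals did not differ detectably, with a median log2 ratio of SDs, stressed over control, of -0.72 with 10 arrays (exact permutation p = 0.143) and -0.14 without control mouse 1 (exact permutation p = 0.738).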

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

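Of the tests in this part, those of large intestine tissue over genes above the filter, of epithelial loss and RNA degradation in control mouse 1, of time of day, of Peyer patch content, and the regroupings for counts of genes were chosen after the result was seen. The tests of lymphocyte loss, of RNA quality in the list means and the regroupings for counts of lists were set out before their own values were seen.

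An array was singled out where its gap to the nearest other array was a large part of the range of its group (Dixon's criterion). This was so in 26 of 152 groups of 5 values tested, where chance gives about 7.6, and 17 of the 26 concerned control mouse 1. The chance figure is only a rough guide, since the large intestine score and the named genes were picked from these data. Many of the values are also related to one another. Each value here is the array singled out minus the mean of the other 4 arrays of its group. The large intestine score of control mouse 1 stood apart at 2.53, and its mean correlation with the other arrays at -0.0474. Its list means stood apart for absorptive enterocytes at -3.20, Paneth cell products at -2.73, bile acid handling at -2.01, epithelial defence at -1.01, cholesterol synthesis at -0.944 and intestinal stem cells at -0.576. In the other direction, it stood apart for xenobiotic metabolism at 1.08, enteric neurons and glia at 0.655, goblet cell products at 0.574 and mitochondrial respiration at 0.25. Among named genes it stood apart for Serpina1b at -5.55, Prr15 at -1.50, Cpn1 at 2.21, Dixdc1 at 2.06 and Ppargc1a at 1.37.

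Other arrays stood apart in fewer values. Stressed mouse 4 did so in the large intestine score at 1.55 and in Dixdc1 at 0.613. Stressed mouse 2 did so in Prss27 at 1.05 and in the Paneth cell products list at 0.0944, and stressed mouse 3 in Mzb1 at 0.646. In stressed mouse 1 a kappa variable segment stood apart at -0.742 and the monoamine and tryptophan handling list at -0.13. Control mouse 5 stood apart in Reg4 at 0.699 and in the junction list at -0.161.

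Control mouse 1 lacked much of the ileal epithelial programme and had high levels of several large intestine genes. A loss of villus and crypt epithelium alone cannot raise epithelial genes such as Car1 (8.49 higher than in the other 4 controls) and Cyp2c55 (6.91 higher), although a test on 10 posterior Hox genes, set out first, gave a median of 0.398 and did not argue against it. A 3' to 5' ratio of 0.5939, inside the range of the other 9 arrays, argues against RNA degradation. Large intestine tissue in the sample stays open and may account for the pattern, since the median over 17 such genes, listed once this mouse had stood apart, was 0.575, between the bounds of 0.5 and 1 set against and for it, and passed the upper bound at 1.09 only over the 10 genes above the filter, a restriction chosen after those values were seen. The design gives no group that sets this mouse apart, so no biological explanation was tested.

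Epithelial defence genes were lower in stressed mice without control mouse 1, with a list mean difference of -0.975 ± 0.194 (SE). The difference was -1.05 ± 0.216 (SE) with the 3' to 5' ratio as a covariate, which argues against RNA quality as the whole cause. With the clock phase score it was -0.757 ± 0.17 (SE), a fit that cannot decide on time of day. Of the controls kept, only control mouse 5 scored above any stressed mouse. Its defence list mean, relative to the 10 arrays, was 0.4802, above the highest stressed mouse at 0.0443. Among stressed mice the list mean was highest at the lowest score (mouse 2) and lowest at the highest score (mouse 5). A loss of lymphocytes and their signals cannot be told apart from a change in the epithelium, since the defence list mean minus the T cell list mean differed by -0.389 between groups with an exact permutation p of 0.1429. An effect of the stress, the group of the design, stays open and may act through either. The part of the intestine sampled was not tested as a cause for this list. Retnlb and Saa3 were highest of their groups in control mouse 1 and stressed mouse 4, the arrays with high large intestine genes. Reg3g went the other way and was lowest of all arrays in control mouse 1.

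T cell and intraepithelial lymphocyte genes were lower in stressed mice without control mouse 1, with a list mean difference of -0.587 ± 0.162 (SE). It was -0.857 ± 0.213 (SE) with the B cell and Peyer patch list mean as a covariate, a fit that cannot decide on Peyer patch content. All 5 stressed mice lay below these 4 controls in that mean. Control mouse 5, the highest in it, had the lowest T cell list mean of these controls. With the 3' to 5' ratio the T cell list mean difference was -0.593 ± 0.191 (SE), which argues in the same way against RNA quality. With the clock phase score it was -0.417 ± 0.151 (SE), a fit that cannot decide on time of day. Control mouse 5, at 1.384, was the only one of these controls to score above any stressed mouse. Its T cell list mean was -0.0784, close to the highest stressed mouse at -0.1035. Stressed mouse 2 went the other way, with the lowest stressed score and a list mean of -0.2951. An effect of the stress itself stays open as a hypothesis, and was not tested apart from the groups.

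Regrouping the 9 arrays at random gave a different answer for genes and for lists. Of 100 drawn from the 126 splits of the 9 arrays into 4 and 5, the real split among them, only the real split gave 109 genes. Another split gave at most 47, so such a count is rare among regroupings of these 9 arrays. The set of 9 arrays was put forward, and this test chosen, after the data had been seen, so chance is not excluded for that count. With all 10 arrays the real count was 0 in limma (1069 genes at an unadjusted p under 0.05), which 100 of 100 splits reach by construction (highest other count 0), so that comparison says nothing about chance. For gene lists, with the real split counted, 37 of 100 splits of the 10 arrays gave as many as the real 15 (at most 23). Likewise, 21 of 100 splits of the 9 arrays gave as many as the real 17 (at most 22), so chance cannot be excluded for either count.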

How the results depend on the processing

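Every alternative without control mouse 1, the covariates for the large intestine score and the clock phase score, and the tests of every probe set or of an adjusted p under 0.1 on those 9 arrays were chosen after the result was seen. With 10 arrays limma called 0 genes (1069 at an unadjusted p under 0.05). It called 2 with the mean of a gene's probe sets, 2 with quantile normalization, 2 at an adjusted p under 0.1, 8 with the large intestine score as a covariate and 41 with array weights. Leaving out each mouse gave 0 to 109 genes, with 109 without control mouse 1 and 2 without stressed mouse 2. The count of 109 without control mouse 1 became 189 with quantile normalization, 169 with limma's trend and robust options, 302 with the smooth muscle list mean as a covariate, 466 at an adjusted p under 0.1 and 70 with every probe set tested. It became 31 with the 3' to 5' ratio as a covariate and 0 with the B cell and Peyer patch list mean, 0 with the large intestine score and 0 with the clock phase score. Leaving out each further mouse gave 6 (without stressed mouse 4) to 154 (without stressed mouse 2). A mouse left out means fewer samples; otherwise the cause was not tested. The 15 lists shifted with 10 arrays became 0 with an estimated correlation and 0 with fry. The 17 without control mouse 1 became 10 with the B cell and Peyer patch list mean as a covariate (8 of them among the 17), 1 with an estimated correlation and 8 with fry (7 of them among the 17). The separation of the groups ranged from 13.6% to 30.2% when each of the 10 mice was left out, the highest without control mouse 1. The spread without control mouse 1 ranged from -0.3545 to 0.1891 on leaving out each further mouse and reversed at 0.1891 without control mouse 3, with the cause not tested. Directions of the named genes reversed in 0 of 367 alternatives for 16 genes with 10 arrays, and in 0 of 523 for 24 genes without control mouse 1, of which 246 missed the threshold. These genes were picked for their p or change on the same arrays, so a reversal was unlikely in advance. Mice of the 2 groups share replicate numbers. With the number as a replicate block, limma called 0 genes and camera 17 lists with 10 arrays, and 95 genes and 19 lists without control mouse 1, where the call for fatty acid synthesis ended (adjusted p = 0.0622). Mice of the same number correlated at 0.13, 0.28, 0.0045, -0.30 and 0.042 after group means were removed, and only number 2 correlated best with its own number. Genes near the array background have their changes understated at this signal.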

Other observations

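The exact permutation tests of list means and the comparisons without control mouse 1 beyond its planned omission were chosen after the result was seen.

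Further immune lists were lower in stressed mice in limma's camera, with 10 arrays and without control mouse 1. Neutrophil genes (7 of 7 lower) had adjusted p of 0.00808 and 0.000610, and 0.297 and 0.0948 as adjusted p with an estimated correlation. Their mean differed by -0.19 with 10 arrays (exact permutation p = 0.0476, and 0.160 adjusted over 37 lists) and by -0.26 without control mouse 1 (exact permutation p = 0.00794, and 0.0367 adjusted), where Ltf, which encodes lactoferrin, fell by 0.61 ± 0.11 (SE, limma adjusted p = 0.0330). With 10 arrays Ltf differed by -0.39 ± 0.22 (SE), and in control mouse 1 it was below every stressed mouse. Macrophage and dendritic cell genes had adjusted p of 8.69e-05 and 3.09e-05, and adjusted p = 0.297 and 0.308 with an estimated correlation, with 0 of 26 members past the threshold over the list alone in limma. Cytokine and chemokine genes had adjusted p of 0.0208 and 0.0168, and adjusted p = 0.165 and 0.152 with an estimated correlation. Among the 19 measured, without control mouse 1, 5 fell and 1 rose over the list alone, and 1 passed over all genes, the chemokine Ccl22, which fell by 0.54 ± 0.08 (SE, limma adjusted p = 0.0245) and differed by -0.49 ± 0.09 (SE) with 10 arrays. That list lost its call without control mouse 2 (adjusted p = 0.0860 with 10 arrays and 0.0576 without control mouse 1 as well) and, with 10 arrays, without control mouse 5 (adjusted p = 0.0554). Type 17 immunity genes had adjusted p of 0.00658 and 0.0168, and adjusted p = 0.165 and 0.176 with an estimated correlation. Tuft cell genes had adjusted p of 0.000196 and 0.00927, and adjusted p = 0.165 for both with an estimated correlation. The tuft cell call without control mouse 1 ended without control mouse 5 (adjusted p = 0.0875). With the B cell and Peyer patch list mean as a covariate, the calls without control mouse 1 ended for tuft cells (adjusted p = 0.718), type 17 immunity (adjusted p = 0.285) and cytokines (adjusted p = 0.1001). With 10 arrays that covariate ended the calls for neutrophils (adjusted p = 0.308), cytokines (adjusted p = 0.237) and type 17 immunity (adjusted p = 0.0657). Leaving out the lowest 60 percent of probe sets ended the calls without control mouse 1 for tuft cells (adjusted p = 0.0879), type 17 immunity (adjusted p = 0.0591) and cytokines (adjusted p = 0.0970), and that for cytokines with 10 arrays (adjusted p = 0.0645).

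Another 5 lists were called in camera without control mouse 1 and not with all 10 arrays, and the difference between the fits was not tested. Array weights with all 10 arrays called each of them in the same direction as without that mouse, at adjusted p of 0.00626 for enteric neurons and glia, 0.0418 for fatty acid synthesis, 0.00626 for adipose genes, 0.000886 for exocrine pancreas and 0.0202 for the unfolded protein response. With 10 arrays the smooth muscle list mean as a covariate also gave a call for enteric neurons and glia (adjusted p = 0.00236). The B cell and Peyer patch list mean as a covariate there called adipose genes lower (adjusted p = 0.0288). It called exocrine pancreas (adjusted p = 0.0105) and unfolded protein response genes (adjusted p = 0.0108) higher. These directions were opposite to those of the calls without control mouse 1. Enteric neuron and glia genes were higher (adjusted p = 0.00131, and adjusted p = 0.308 with an estimated correlation), among them the synaptic gene Snap25, which rose over the list alone by 0.53 ± 0.13 (SE) and differed by 0.31 ± 0.23 (SE) with 10 arrays. Fatty acid synthesis genes were higher (adjusted p = 0.0268, and adjusted p = 0.308 with an estimated correlation), and Fasn, the fatty acid synthase, rose over the list alone by 0.38 ± 0.11 (SE) and differed by 0.23 ± 0.17 (SE) with 10 arrays. The call for fatty acid synthesis ended without control mouse 5 (adjusted p = 0.106) and without stressed mouse 1 (adjusted p = 0.0711), and with the 3' to 5' ratio (adjusted p = 0.0630) or the large intestine score (adjusted p = 0.0562) as a covariate. Adipose genes were higher (adjusted p = 0.0134, and adjusted p = 0.453 with an estimated correlation), a call that ended without control mouse 5 (adjusted p = 0.106), stressed mouse 4 (adjusted p = 0.0677) and stressed mouse 5 (adjusted p = 0.0529). Exocrine pancreas genes were lower (adjusted p = 0.00326, and adjusted p = 0.421 with an estimated correlation), a call that ended without control mouse 5 (adjusted p = 0.155). Unfolded protein response genes were lower (adjusted p = 0.00598, and adjusted p = 0.421 with an estimated correlation), a call that ended without control mouse 2 (adjusted p = 0.0863). With the B cell and Peyer patch list mean as a covariate, the calls for fatty acid synthesis (adjusted p = 0.490), adipose genes (adjusted p = 0.892), exocrine pancreas (adjusted p = 0.220) and the unfolded protein response (adjusted p = 0.0762) ended. The large intestine score as a covariate ended those for adipose genes (adjusted p = 0.241) and the unfolded protein response (adjusted p = 0.0780), and leaving out the lowest 60 percent of probe sets that for exocrine pancreas (adjusted p = 0.134). With 10 arrays the unfolded protein response list was not called (adjusted p = 0.990), and its test and median (0.01) were positive while its mean difference (-0.02) was negative.

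Some hormone and early response genes moved within lists that camera did not call at the preset correlation. Without control mouse 1, fry called the enteroendocrine list higher (adjusted p = 0.0270), as did camera in 11 of 22 other settings. With 10 arrays camera did so in 1 of 23. Such calls also came for other lists, with xenobiotic metabolism higher in 13 and PPAR alpha targets in 9 settings without control mouse 1. With 10 arrays, intestinal stem cells were higher in 10 and retinoid metabolism in 9. Of 17 measured enteroendocrine genes, 5 rose over the list alone without control mouse 1, among them Gcg, the precursor of glucagon-like peptides, by 0.38 ± 0.11 (SE) against 0.37 ± 0.11 (SE) with 10 arrays, and 1 fell. The gene that fell was Cck, which encodes cholecystokinin and fell by 0.52 ± 0.09 (SE, limma adjusted p = 0.0301 over all genes). With 10 arrays 0 of the 17 passed over the list alone in limma, and Cck differed by -0.24 ± 0.25 (SE), with control mouse 1 at 4.83, below every stressed mouse. The immediate early gene Fos rose over its list alone with 10 arrays, by 0.80 ± 0.18 (SE), and without control mouse 1, by 0.70 ± 0.17 (SE), while Jun fell by 0.43 ± 0.13 (SE) over the list alone without control mouse 1 and differed by -0.42 ± 0.13 (SE) with 10 arrays. The smooth muscle list was not called in camera with 10 arrays (adjusted p = 0.363) or without control mouse 1 (adjusted p = 0.731), but was lower in both with the 3' to 5' ratio as a covariate (adjusted p = 1.27e-05 and 0.000470) and, with 10 arrays, without stressed mouse 1 (adjusted p = 0.00247).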
